A study of Mus musculus with 18 samples.

How the data were processed

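RNA sequencing was measured in 18 mouse samples. They comprised 12 liver tumors in 4 groups of 3, 3 samples of SB1 cells and 3 samples of SY1 cells. Tumors had been raised with an activated AKT (myr-AKT) together with 1 of 2 forms of YAP, called YAP-S (S127A) and YAP-SY (S127A/Y357F). The tumors of each model were labelled as cholangiocarcinoma (CCA) or as mixed tumors. SB1 and SY1 are cell lines whose genotype labels are those of YAP-S CCA and YAP-SY CCA. Numbers in the sample names were taken as animal or replicate numbers. The labels do not say that they pair tumors across the models, and the main fit used no pairing. For numbers 3, 5 and 9, which occur in both models, deviations of same-numbered tumors from their group means correlated by 0.18, 0.35 and 0.09. Without the same values for differently numbered tumors, this does not settle whether they pair.

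The deposited tumor values were counts per gene that the authors had adjusted in some way before deposit. What was corrected, and how, is not stated. In 11 of the 12 tumor libraries fewer genes held a count of 2 than a count of 3. Whether uncorrected counts of these tumors show the same cannot be checked here. The table was not scaled to depth. Per the labels, STAR was the aligner and mm10 the genome build; no version, gene annotation release or counting tool is given. The SB1 values were deposited as raw counts per gene in a table of their own. That table holds 3 more columns, whose names match no sample label. They were not used, and so the planned SY1 against SB1 comparison and the test of cell line genes in tumors could not be made.

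Of 43346 genes in the tumor table, 27 symbols had been turned into dates by a spreadsheet and were restored from their Ensembl identifiers. Genes with low counts were removed with filterByExpr by group, which left 18318 genes. Library sizes were scaled by TMM, and CPM values refer to these scaled libraries. All 12 tumors entered a single fit with 1 term per group in edgeR 4.0.16 under R 4.3.3. Contrasts were tested with the quasi-likelihood F-test (glmQLFit and glmQLFTest). The adjusted p is that of Benjamini and Hochberg over all tested genes, with a threshold of 0.05. The 6 contrasts were YAP-SY against YAP-S within CCA, within mixed tumors and over both histologies, the difference of the effect between histologies, and CCA against mixed tumors within each model. Standard errors (SE) of log2 fold changes come from the same fit. Total counts ran from 30656499 to 130035221 per tumor and from 25341968 to 30541185 per SB1 sample. Intervals from depth alone would cover counting error only, and none are given because the fit estimates the spread between tumors.

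Of 45 gene lists written from textbook knowledge, 40 were tested with camera in limma 3.58.1. This required at least 5 measured members and left out a panel of 21 single genes and a list of sex-linked genes. Camera used a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Each list's adjusted p with an estimated correlation is printed beside its result. The fry test was run as well; it asks whether a list's genes move 1 way on balance and compares them with no other genes. Counts of list members past the threshold are also given adjusted over the list alone. List scores are the mean log2 CPM of the measured members, with a prior count of 1. The lists covered YAP-TEAD targets, Hippo components, kinases and phosphatase of the mutated YAP tyrosine, cholangiocyte, hepatocyte and oncofetal genes, Wnt and pericentral genes, Notch, and mucins. They also covered integrins and laminins, epithelial junctions, mesenchymal transition, fibroblasts, endothelium, 6 blood and immune cell types, cell cycle, metabolism, and signalling or stress responses. Pancreatic, muscle and mitochondrial genes had too few measured members for a test; mitochondrial transcripts were at 0.

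The samples, groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. By that rule a comparison names the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups. Predicted genes and antigen receptor segments were left out. The rule adds the 3 members with the smallest p of each list past its threshold, the panel, Yap1 and Akt1 in every sample, and the 4 largest differences in each direction between the histologies. The text gives the values of only some of the genes so named, and a few are not reported here. Genes marked as chosen after their values were seen lie outside the rule. Where more than 3 members of a list are named, others of them may lie outside it too.

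Each result was recomputed under other settings, and the closing section gives their effect. Planned from the start were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights and no count filter. A filter of 1 CPM in 3 libraries, fits of the compared groups alone, no histology term, the animal number as a replicate block and a minimum log2 change of 1 were planned too. So were leaving out each tumor and leaving out the tumors with a second naming of YAP-SY in the table. After the data had been seen, library size alone, upper quartile factors, log2 Akt1 as a covariate and a library batch were added. The batch was read from the ratio of genes at 3 counts to genes at 2. That ratio parted 4 tumors, 1 per group, from the other 8. The labels give no batch. These 4 were also the 4 libraries with the fewest counts, at 30656499 to 43188347 against 46149338 or more in the others. The split cannot tell a batch from depth, and batch below means this split only. Both a batch term and a fit of the 8 tumors were run. The YAP-SY CCA libraries were also rescaled by a single factor, in steps of 0.1 from -1 to 1 on the log2 scale, and the CCA contrast was tested again at each step. Groupings other than the labelled one were counted over all splits of 3 against 3, or over 100 random splits within histology. The whole procedure was tested on simulated data: 100 genes with a 2-fold and 100 with a 4-fold change were added to groups without differences. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.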

Results

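Gene expression was compared between liver tumors driven by activated AKT and YAP-S and tumors driven by AKT and YAP-SY. YAP-S carries S127A, a change that keeps YAP in the nucleus, and YAP-SY carries S127A/Y357F, which also removes a tyrosine that Src family kinases phosphorylate. For each model, 3 CCA and 3 mixed tumors were sequenced. YAP-S CCA tumors 3, 4 and 5 held 84515613, 75093769 and 32999594 counts, and YAP-S mixed tumors 2, 7 and 9 held 49507941, 60698479 and 30656499. YAP-SY CCA tumors 1, 6 and 8 held 53228550, 46149338 and 43188347, and YAP-SY mixed tumors 3, 5 and 9 held 32303243, 65774097 and 130035221. Log2 CPM correlated by 0.9745 to 0.9911 between tumors of a group across genes, which are not independent replicates. The highest value between any 2 tumors, 0.9915, joined YAP-SY mixed tumor 3 and YAP-S mixed tumor 2. YAP-SY CCA tumor 1 stood apart on the first principal component, which held 37% of the variance, at -108 against -35.7 and -36.4 in tumors 6 and 8. It also had the fewest genes with a count, 18207, against 20440 to 24391 in the other tumors. Alb alone took 4.39% to 8.87% of a tumor's counts.

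The introduced plasmids carry forms of YAP and AKT, whose mouse genes are Yap1 and Akt1. The labels do not give the species of the plasmid sequences, so how far plasmid reads count towards these mouse genes is not known. Counts from the plasmids and from the animals' own genes cannot be told apart here. Yap1 and Akt1 values therefore do not measure plasmid expression. Akt1 (ENSMUSG00000001729, mm10 chromosome 12, 112653821 to 112674884) was at 744, 483 and 834 CPM in YAP-S CCA tumors 3, 4 and 5 and at 199, 105 and 276 CPM in YAP-SY CCA tumors 1, 6 and 8. YAP-S mixed tumors 2, 7 and 9 held 384, 931 and 256 CPM of Akt1, and YAP-SY mixed tumors 3, 5 and 9 held 416, 520 and 380 CPM. In CCA it was 3.55-fold lower in YAP-SY (log2 fold change -1.83, SE 0.44, adjusted p 0.00643). In mixed tumors Akt1 did not pass the threshold (log2 fold change -0.26, adjusted p 0.999), nor did the difference between the histologies (-1.57, adjusted p 0.096), which passed under library size alone (-2.07, adjusted p 0.0427). Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) was at 106, 108 and 90.9 CPM in YAP-S CCA and at 102, 83 and 88.2 CPM in YAP-SY CCA tumors. It was at 99.8, 110 and 114 CPM in YAP-S mixed and at 90.2, 73.6 and 87.4 CPM in YAP-SY mixed tumors. Yap1 did not pass the threshold in CCA (log2 fold change -0.16, SE 0.13, adjusted p 0.364), in mixed tumors (-0.37, SE 0.13, adjusted p 0.999) or over both (-0.26, adjusted p 0.0547). Under library size alone Yap1 was at 124, 124 and 118 CPM in YAP-S CCA and at 84.6, 64.4 and 73.4 CPM in YAP-SY CCA tumors, and passed in CCA (-0.716, adjusted p 0.000699) and over both (-0.572, adjusted p 0.00103). In mixed tumors it was then at 99.9 to 120 CPM in YAP-S and 78.4 to 86.4 CPM in YAP-SY, with no overlap by either scaling, and did not pass (-0.428, adjusted p 1). With upper quartile factors it passed over both (-0.28, adjusted p 0.0405).

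**Figure D1:**
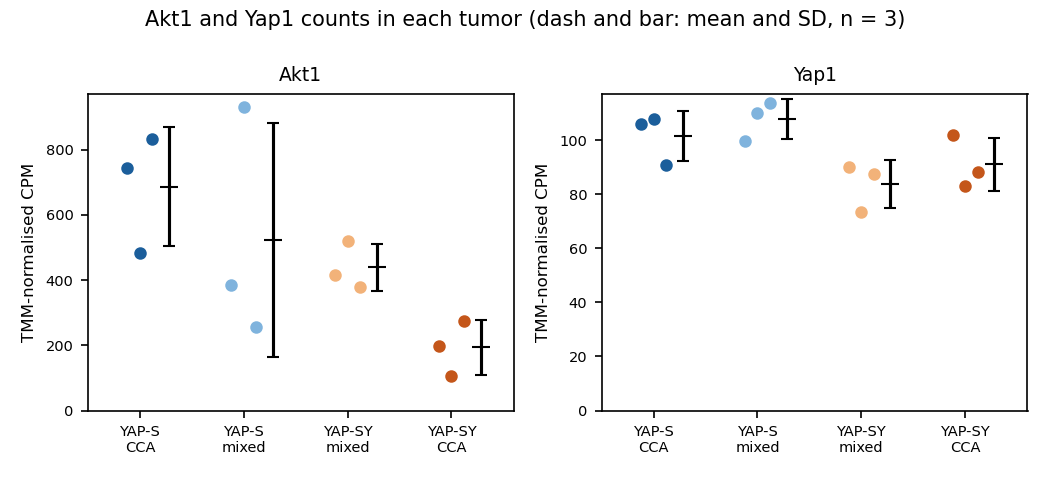
TMM-normalised CPM of Akt1 and Yap1 in each of the 12 tumors (points), with the mean and SD of each group of 3. Akt1 in the YAP-SY CCA tumors, at 105 to 276 CPM, lay below all 3 YAP-S CCA tumors, while Yap1 ran from 73.6 to 114 CPM over all groups.

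The comparison of YAP-SY with YAP-S in CCA tumors asks what loss of the phosphorylated YAP tyrosine changes in tumors labelled as bile duct cancer. YAP-SY CCA tumors held less RNA of YAP targets, bile duct genes and stroma and more RNA of hepatocyte genes. Ankrd1, a direct target of YAP and its TEAD partners, was 10.2-fold lower, at 153 ± 37.8 CPM in YAP-S and 14.9 ± 7.17 CPM in YAP-SY (SD, n = 3). Sox9, a transcription factor of bile duct cells, was 3.99-fold lower (56.8 ± 6.95 to 14.2 ± 6.01 CPM). Col1a1, a chain of the main fibrous collagen, was 10.9-fold lower (286 ± 78.9 to 26.2 ± 17.2 CPM), with a log2 fold change of -3.45, or -4.13 without YAP-SY CCA tumor 8. Alb, the serum protein of hepatocytes, was 2.85-fold higher (37000 ± 2680 to 105000 ± 8100 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7171 of 18318 genes passed, 3358 higher and 3813 lower in YAP-SY; 8811 had an unadjusted p under 0.05, where chance gives 916. In 52.6% of the tested genes the 3 tumors of each group did not overlap, against 10% by chance for 3 against 3. Scaling by library size alone moved the median of all genes by -0.56 on the log2 scale and split 8824 called genes into 760 higher and 8064 lower, so every change in this comparison is relative to the TMM scale.

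YAP-TEAD targets fell as a group: of 21 measured members 15 fell and 1 rose, or 17 and 1 adjusted over the list alone, with a median log2 fold change of -1.51. The list's adjusted p was 0.126 with an estimated correlation. Ctgf, a secreted matrix protein and standard YAP readout, fell 5.96-fold (log2 fold change -2.58, SE 0.27, adjusted p 0.000107, 165 ± 28.2 to 27.7 ± 9.44 CPM, n = 3). Cyr61, a related secreted protein, fell 2.77-fold (101 ± 21 to 36.3 ± 2.06 CPM). Ankrd1 had a log2 fold change of -3.35 (SE 0.37, adjusted p 0.000113), Igfbp3, a binding protein of growth factors, -1.76, and Ptpn14, a YAP-binding phosphatase, -1.68. The single riser was Dock5 (0.52, chosen after its values were seen), whose call ended without YAP-S CCA tumor 3 (0.40) and which turned to -0.05 under library size alone. Ctgf lies on chromosome 10 (ENSMUSG00000019997, 24595442 to 24598683), Ankrd1 on chromosome 19 (ENSMUSG00000024803, 36111965 to 36119844) and Cyr61 on chromosome 3 (ENSMUSG00000028195, 145646971 to 145649985). The Hippo pathway list did not pass (camera adjusted p 0.198, 0.48 with an estimated correlation). In it Tead1, Tead2, Wwtr1 and Amotl2 fell and Mob1b and Lats1 rose, the same counts adjusted over the list alone; apart from Amotl2 these were named after their values were seen. The call of Lats1 ended in 4 of 6 leave-outs of a tumor (YAP-S CCA 3, 4 and 5 and YAP-SY CCA 6, lowest value 0.25) and turned to -0.20 under library size alone, where Mob1b also lost its call. Among the kinases and phosphatase that act on the mutated tyrosine, 6 of 11 fell, by either adjustment (median -0.47, 0.407 with an estimated correlation), including Src (-2.02), Frk (-1.05) and Lck (-2.82), the last a kinase of T cells, whose markers fell too (Trac by 2.35).

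Bile duct genes were lower. Of 20 cholangiocyte markers 16 fell (18 lower and 1 higher adjusted over the list alone), with a median of -1.88 and an adjusted p of 0.17 with an estimated correlation. Sox9 had a log2 fold change of -2 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, adjusted p 0.00112). Cd24a, a surface protein of bile duct and progenitor cells, had a log2 fold change of -2.98 and Ehf, an epithelial transcription factor, -2.50. Spp1, which encodes osteopontin, was at 8490 ± 1810 CPM in YAP-S and 3270 ± 710 CPM in YAP-SY (log2 fold change -1.37, n = 3), and its call ended without YAP-SY CCA tumor 6 (-1.26) or YAP-S CCA tumor 5 (-1.20). Krt19, a bile duct keratin, had a log2 fold change of -3.20; its call ended without YAP-S CCA tumor 4 (-2.82), YAP-SY CCA tumor 6 (-2.82) or YAP-SY CCA tumor 8 (-2.73), and its value was -4.93 without YAP-SY CCA tumor 1. Epcam, an epithelial adhesion protein, had -1.23 and lost its call without YAP-S CCA tumor 3 or 5 (-1.14 each) or YAP-SY CCA tumor 6 (-1.01) or 8 (-1.26). Krt7 did not pass (-2.12, SE 0.87, adjusted p 0.0704). Notch pathway genes, which direct bile duct fate, fell in 12 of 13 by either adjustment (median -1.11, 0.126 with an estimated correlation), among them the targets Heyl (-1.94) and Nrarp (-1.64). Integrins and laminins of epithelium fell in 9 of 13, again by either adjustment (median -1.66, 0.13 with an estimated correlation). Examples were Itgav (-1.66) and Lama5 (-2.33). The cholangiocyte marker score was 4.68 ± 0.134 in YAP-S CCA and 2.66 ± 0.702 in YAP-SY CCA tumors (SD, n = 3). It was 4.01 ± 0.439 in YAP-S mixed and 4 ± 0.329 in YAP-SY mixed tumors. By this score YAP-SY tumors labelled CCA held less bile duct RNA than either mixed group. Their hepatocyte identity score, 11.4 ± 0.147, was above the 10.7 of each mixed group.

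Stromal and matrix genes were lower. Fibroblast and stellate cell markers fell in 16 of 18, by either adjustment, with a median of -2.03 and an adjusted p of 0.12 with an estimated correlation. Acta2, the smooth muscle actin of activated fibroblasts, had a log2 fold change of -2.65, the collagen cross-linking enzyme Lox -2.93 and the matrix protein Postn -1.81. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had -3.45 (SE 0.50, adjusted p 0.000366). Of 13 mesenchymal transition genes 8 fell and 1 rose, or 8 and 2 adjusted over the list alone (median -1.55, 0.15 with an estimated correlation). Vim, an intermediate filament of mesenchymal cells, had -2.64, Sparc -2.10 and Tnc -3.15. The riser was the cadherin Cdh2 (0.47), which lost its call without YAP-S CCA tumor 5 (0.39) and turned to -0.09 under library size alone. TGF-beta response genes fell in 11 of 12 by either adjustment (median -1.48, 0.12 with an estimated correlation), with Tgfb3 at -3.50 and Thbs1 at -2.97. Cdh2 was chosen after its values were seen.

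Genes of acute inflammation, antigen presentation and T and NK cells were lower. NF-kB and acute inflammation genes fell in 14 of 17 (15 adjusted over the list alone; median -1.90, 0.138 with an estimated correlation), among them the leukocyte adhesion protein Vcam1 (-2.46), the cytokine gene Tnf (-3.06) and Nfkb2 (-2.16). Antigen presentation genes fell in 10 of 12 by either adjustment (median -2.68, 0.317 with an estimated correlation), as in H2-Ab1 (-2.90), a class II chain, and Itgax (-2.42), an integrin of dendritic cells. T and NK cell markers fell in 10 of 18 (14 adjusted over the list alone; median -1.77, 0.495 with an estimated correlation), including Trac (-2.35). Ptprc, carried by all white blood cells, fell 2.26-fold (54.9 ± 17 to 24.3 ± 4.86 CPM, n = 3, adjusted p 0.0127). Of 20 interferon response genes 7 fell by either adjustment (median -0.50, 0.576 with an estimated correlation; fry adjusted p 0.0659), as in Oasl2 (-1.84) and Gbp2 (-2.68), and the list's score in YAP-SY CCA tumor 8 (5.49) was above those of YAP-S CCA tumors 3 and 5 (5.31 and 5.38).

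Neutrophil markers as a list held little RNA. Their list score was 0.0413 ± 0.132 in YAP-S CCA and -2 ± 0.666 in YAP-SY CCA tumors (mean log2 CPM, SD, n = 3). Large folds can thus rest on low counts. Among these markers 5 of 9 fell (6 adjusted over the list alone, 0.17 with an estimated correlation). They were Il1r2 (-3.57), Csf3r (-1.22), Ltf, Cxcr2 and Mmp8; Mmp8 was at 0 in all 3 YAP-SY CCA tumors and no fold is given. Csf3r lost its call without YAP-S CCA tumor 4 (-1.09). Ltf and Cxcr2 each lost it in 4 of 6 leave-outs, in both cases without YAP-S CCA tumor 3 or YAP-SY CCA tumor 8. Ltf also lost it without YAP-SY CCA tumor 1 or YAP-S CCA tumor 5 (-3.37 to -2.83) and reached -7.28 without YAP-SY CCA tumor 6, and Cxcr2 without YAP-S CCA tumor 4 or YAP-SY CCA tumor 6 (-1.56 to -1.40). Immediate early genes fell in 5 of 13 (7 adjusted over the list alone; median -1.11, 0.407 with an estimated correlation): the transcription factors Egr2 (-3.00), Fos (-1.50), Maff and Jun, and Ier3 (-3.52). Jun lost its call without YAP-S CCA tumor 3 or YAP-SY CCA tumor 1 or 6 (-0.70 to -0.52). Ltf and Jun were chosen after their values were seen.

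Cell cycle, p53, hypoxia and glycolysis genes were lower. All 20 G2 and M phase genes fell, by either adjustment (median -1.11, 0.332 with an estimated correlation), as in Aurkb (-1.89), a mitotic kinase, and Top2a (-1.58), which untangles replicated DNA. Mki67, carried by dividing cells, fell 2.35-fold (108 ± 9.11 to 45.7 ± 6.9 CPM, n = 3, adjusted p 0.00289). Of 18 S phase genes 14 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -1.36, 0.317 with an estimated correlation), with the helicase subunit Mcm3 at -1.72. Of 17 p53 targets 11 fell by either adjustment (median -0.69, 0.126 with an estimated correlation), among them the cell cycle inhibitor Cdkn1a (-1.55) and Phlda3 (-2.76), and Perp rose (0.89). Hypoxia response genes fell in 9 of 16 and rose in 2, or 10 and 3 adjusted over the list alone (median -1, 0.39 with an estimated correlation). Car9, a carbonic anhydrase induced by low oxygen, had -3.97 and Ddit4 -2.30, while Bnip3 and Pdk1 rose. Perp, Bnip3 and Pdk1 lost their calls under library size alone, and Pdk1 also without YAP-S CCA tumor 4 or 5 or YAP-SY CCA tumor 6 or 8 (0.48 to 0.64). Glycolysis genes fell in 10 of 17 by either adjustment (median -1.03, 0.393 with an estimated correlation), as in Pfkp (-2.73) and Pkm (-2.31), the muscle form of pyruvate kinase. Bnip3 and Pdk1 were chosen after their values were seen.

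Hepatocyte genes were higher. Of 22 hepatocyte identity genes 18 rose (19 adjusted over the list alone), with a median of 1.27 and an adjusted p of 0.17 with an estimated correlation. Alb (ENSMUSG00000029368, chromosome 5, 90460889 to 90476603) had a log2 fold change of 1.51 (SE 0.21, adjusted p 0.000283), Apob, the core protein of very low density lipoprotein, 1.56, and Ttr, a carrier of thyroid hormone, 0.93. Hepatocyte transcription factors rose in 9 of 15 by either adjustment (median 0.74, 0.155 with an estimated correlation). Hnf4a, the central transcription factor of hepatocytes (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910), rose 2.13-fold from 340 ± 55.8 to 723 ± 113 CPM (n = 3, adjusted p 0.00143). Nr1h4, the bile acid receptor, rose by 1.07 and Cebpa by 1.09. Complement and coagulation genes rose in 21 of 23 by either adjustment (median 1.14, 0.17 with an estimated correlation), as in coagulation factor F5 (1.44). Library size alone ended the calls of Ttr and Cebpa. Afp, a fetal liver protein, did not pass (-0.45, SE 0.86, adjusted p 0.714).

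Liver metabolism genes were higher as well. Cytochrome P450 genes rose in 14 of 16 by either adjustment (median 1.25, 0.17 with an estimated correlation); Cyp2e1 rose 2.86-fold (2650 ± 707 to 7580 ± 1600 CPM, n = 3) and Cyp4a10, a fatty acid hydroxylase, by 2.05 on the log2 scale. Bile acid genes rose in 13 of 14 (14 adjusted over the list alone; median 1.29, 0.17 with an estimated correlation), as in Slc10a1 (1.80), which takes bile acids into hepatocytes, Abcb4 (1.32) and Akr1d1 (1.22). Fatty acid oxidation genes rose in 12 of 15 (13 adjusted over the list alone; median 0.96, 0.155 with an estimated correlation), among them Acadm (1.08), the medium-chain acyl-CoA dehydrogenase. Urea cycle and amino acid genes rose in 12 of 17 (13 adjusted over the list alone; median 1.11, 0.262 with an estimated correlation), with Cps1 at 1.49 and Tdo2 at 1.76. Nuclear oxidative phosphorylation genes rose in 17 of 20 (19 adjusted over the list alone; median 0.70, 0.17 with an estimated correlation), as in Ndufs1 (1.04) and Sdha (0.93).

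Lipid synthesis and pericentral genes moved less evenly. Cholesterol synthesis genes rose in 11 of 20 and fell in 1, or 12 and 1 adjusted over the list alone (median 0.58, 0.42 with an estimated correlation). Sc5d rose by 1.28 and the regulator Srebf2 fell by 0.74, the latter chosen after its values were seen and not past the threshold without YAP-S CCA tumor 3 or YAP-SY CCA tumor 1 or 6 (-0.71 to -0.61). Of 17 fatty acid synthesis genes 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (0.407 with an estimated correlation), and the median of 0.51 turned to -0.05 under library size alone. Acaca (1.01) and Elovl6 (0.96) rose and lost their calls under that scaling, while the desaturase Scd2 fell by 1.63; Fasn did not pass (0.09, SE 0.33, adjusted p 0.855). Of 16 Wnt and pericentral genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.61, 0.48 with an estimated correlation). Slc1a2 rose by 1.57 and Tnfrsf19 fell by 1.44. Glul, the glutamine synthetase of hepatocytes around the central vein, was at 614 ± 193 and 1010 ± 114 CPM (n = 3, log2 fold change 0.71, adjusted p 0.0486). Its call ended under library size alone and in 5 of 6 leave-outs of a tumor (YAP-S CCA 3 and 5, YAP-SY CCA 1, 6 and 8; lowest value 0.49), and it turned to -0.09 with log2 Akt1 as a covariate.

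In CCA 30 of 40 lists passed camera, 11 higher and 19 lower; 0 passed with an estimated correlation, where the smallest adjusted p was 0.12, and fry called 29. Endothelial and macrophage markers did not pass (camera adjusted p 0.348 and 0.441; 0.749 each with an estimated correlation) and moved in both directions. Of 17 endothelial markers 2 rose and 6 fell, or 5 and 8 adjusted over the list alone; of 16 macrophage markers 5 rose and 7 fell, or 5 and 8 adjusted over the list alone. A further 7 lists did not pass either, with camera adjusted p from 0.134 to 0.996 (0.557 to 0.997 with an estimated correlation): oncofetal genes, mucins, epithelial junctions, B cells, red blood cells, the unfolded protein response and cytosolic ribosomal proteins. Together 10 of their 78 measured members passed, or 8 adjusted over the list alone. Of the 21 panel genes 17 passed, 5 higher and 12 lower, or 18 adjusted over the list alone; Afp, Yap1, Fasn and Krt7 did not pass over all genes.

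Among genes without overlap between the groups, the 8 largest rises included Moxd1, a copper monooxygenase of unknown substrate, and Clec2h, a lectin gene. Moxd1 (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790) went from 0.294 ± 0.166 to 36.7 ± 41.9 CPM (log2 fold change 6.89, SE 1.76, adjusted p 0.00853, n = 3), and limma-voom did not call it (3.47). Clec2h (ENSMUSG00000030364, chromosome 6, 128662385 to 128677374) went from 3.11 ± 0.68 to 25 ± 17.2 CPM, 8.06-fold higher. Arrdc3, an arrestin domain protein, rose by 2.47 and Abcd2, a peroxisomal fatty acid transporter, by 2.33. Cyp3a59, Cyp3a25, Mup16 and Serpina3j were the other 4, and their values are uncertain because close paralogs may share their reads. Mup16 lost its call without YAP-SY CCA tumor 6 (1.80) or YAP-S CCA tumor 5 (2.19), and Serpina3j without YAP-S CCA tumor 4 (2.37), YAP-SY CCA tumor 6 (1.06) or YAP-S CCA tumor 5 (2.04). With log2 Akt1 as a covariate they turned to -0.35 and -0.66. Among the largest falls were Tubb3 (-5.19), Akr1cl (-5.13), Wisp2 (-4.81), Csmd1 (-4.73), Clca2 (-4.63), Slc16a3 (-4.54) and Dclk1 (-4.46). Wisp2, a secreted matrix protein of the Ctgf family, went from 48.4 ± 5.56 to 1.73 ± 1.09 CPM, and Slc16a3, a lactate exporter, from 19.3 ± 7.3 to 0.83 ± 0.059 CPM.

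Leaving out a single CCA tumor left 5121 to 6869 genes past the threshold in CCA, and a batch term left 6224. Of the 120 genes named as called in this comparison, here and in the closing section, library size alone ended 18 calls, 4 of them with a turn of direction. Log2 Akt1 as a covariate ended 82 calls, 3 with a turn, and the 8 tumors of the larger batch alone ended 27. A minimum log2 change of 1 ended 21, leaving out the tumors with a second naming of YAP-SY ended 9, and limma-voom ended 5, those of Moxd1, Serpina3j, Trac, Cxcr2 and Jun. A batch term ended those of Glul, Clec4f, Pdk1, Cxcr2 and Lats1. Some folds moved by over 1.5 times with their calls kept. Without YAP-SY CCA tumor 1 the log2 fold change was 5.47 in Moxd1, -6.37 in Akr1cl, -5.36 in Clca2, -5.06 in Dclk1, -3.66 in Thbs1 and -2.94 in Il1r2. Without YAP-SY CCA tumor 6 it was 1.85 in Arrdc3 and -5.33 in Il1r2, and without tumor 8 -5.45 in Wisp2 and -3.61 in H2-Ab1. Without YAP-S CCA tumor 3 it was 7.53 in Moxd1, and without tumor 4 -2.09 in Gbp2. The smaller batch held 1 tumor per group and gives no value of its own.

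**Figure D2:**
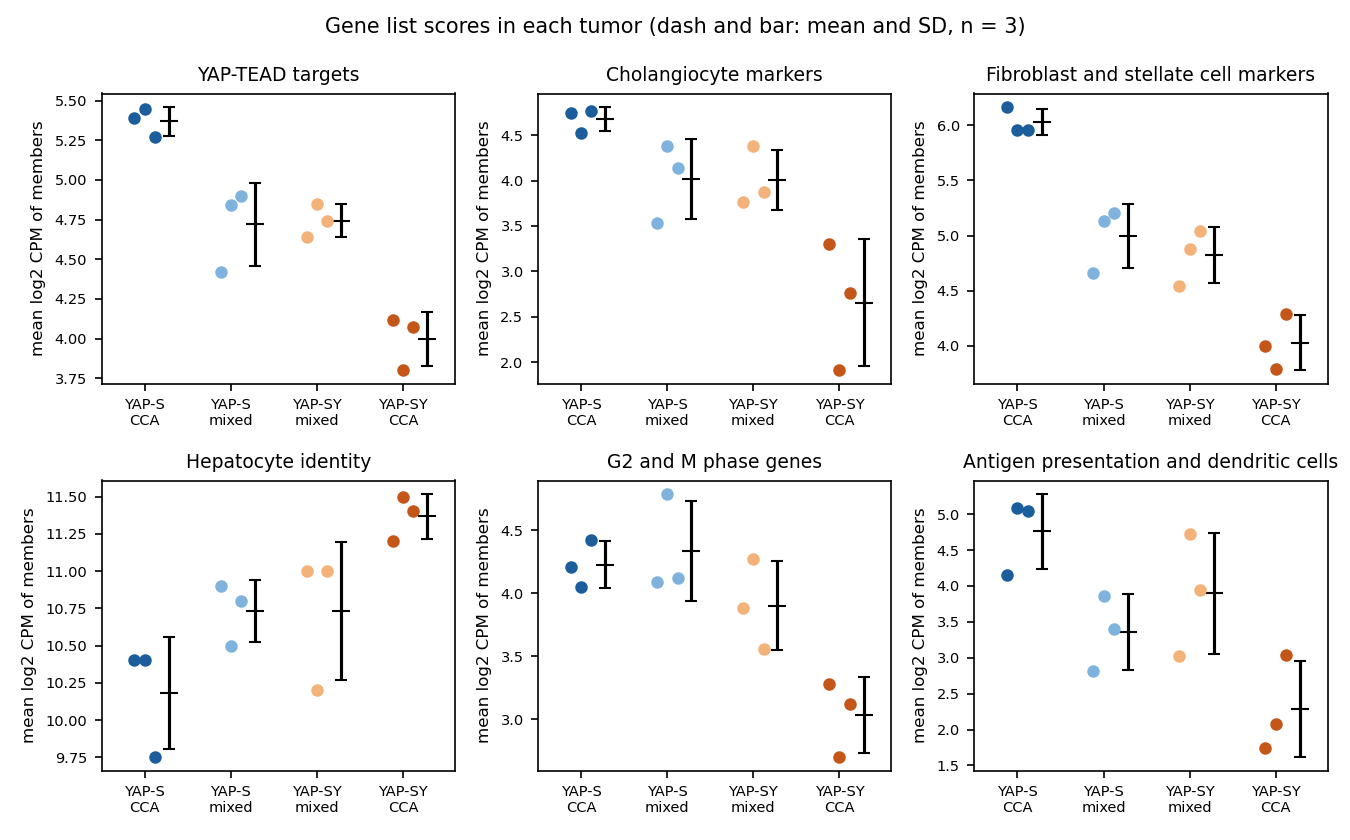
Mean log2 CPM over the measured members of 6 gene lists in each tumor (points), with the mean and SD of each group of 3. The YAP-TEAD score was 5.37 ± 0.0885 in YAP-S CCA and 4 ± 0.173 in YAP-SY CCA, with both mixed groups, at 4.72 ± 0.259 and 4.74 ± 0.102, in between.

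**Figure D3:**
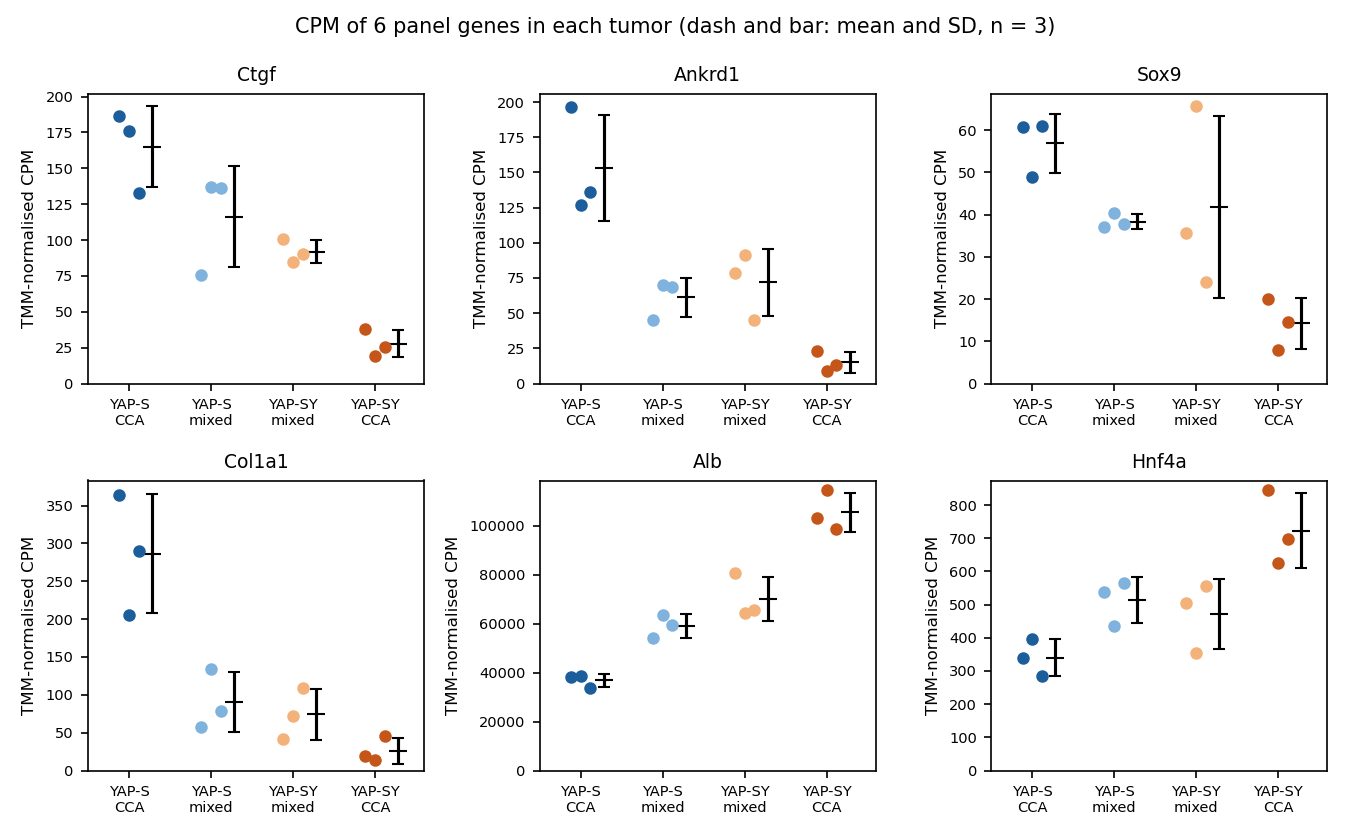
TMM-normalised CPM of 6 panel genes in each tumor (points), with the mean and SD of each group of 3. In Ctgf, Ankrd1, Sox9 and Col1a1 the YAP-SY CCA tumors were lower than the YAP-S CCA tumors, and in Alb and Hnf4a they were higher.

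In mixed tumors, where the same contrast asks for the effect of the tyrosine change outside tumors labelled as CCA, no single gene passed. Alb had a log2 fold change of 0.25 (SE 0.20) and Hnf4a -0.12 (SE 0.20). Ctgf had -0.34 (SE 0.26), Ankrd1 0.23 (SE 0.33), Sox9 0.12 (SE 0.34) and Col1a1 -0.28 (SE 0.45), all with an adjusted p of 0.999. By edgeR's quasi-likelihood test 0 of 18318 genes passed, with a smallest adjusted p of 0.665; 551 had an unadjusted p under 0.05, where chance gives 916. DESeq2 called 9 genes and limma-voom 0, with 1759 at an unadjusted p under 0.05. The 3 tumors of each model did not overlap in 8.35% of the genes, against 10% by chance. Of the panel 0 genes passed, also adjusted over the list alone.

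By camera 9 lists passed in mixed tumors, 5 higher and 4 lower; 0 passed with an estimated correlation (smallest adjusted p 0.684), and fry called 0. G2 and M phase genes had a median of -0.46 (0.684 with an estimated correlation), with Cdk1, the kinase that starts mitosis, at -0.58, and genes of the unfolded protein response a median of -0.38 (0.684). Fibroblast markers (-0.24, 0.778) and glycolysis genes (-0.17, 0.785) were the other 2 lower lists. Cytochrome P450 genes had a median of 0.45 (0.684), with Cyp4a10, for example, at 0.81. B cell markers (0.48, 0.684), T and NK cell markers (0.73, 0.745), antigen presentation genes (0.76, 0.745) and fatty acid oxidation genes (0.17, 0.745) were the other higher lists. In these 9 lists, adjusted over the list alone, 3 cytochrome P450 genes (Cyp4a10, Cyp4a14 and Cyp2a5), 1 B cell marker (Cd79a) and 1 fatty acid oxidation gene (Cyp4a14 again) passed; paralogs may share reads with Cyp4a14, and no member passed over all genes. Among lists that did not pass camera, 1 mucin and gastric gene, Ctse (1.61), and 1 bile acid gene, Akr1d1 (0.587), passed in that way, both named after their values were seen. YAP-TEAD targets had a median of -0.07 but a mean of 0.01, with the test pointing upward (camera adjusted p 0.786, 0.93 with an estimated correlation). Over all comparisons, median, mean and test differed in sign in 12 of 240 list tests, of which 0 were past the threshold.

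Whether the effect of YAP-SY differed between CCA and mixed tumors was tested directly as a difference of log2 fold changes. Ankrd1 had a difference of -3.58 (SE 0.49, adjusted p 0.00292), Ctgf -2.24 (SE 0.37, adjusted p 0.00443) and Cyr61 -1.26 (SE 0.24), each with a fall in CCA and a smaller change in mixed tumors. Col1a1 had -3.17 (SE 0.65), Sox9 -2.12 (SE 0.48), Alb 1.26 (SE 0.29) and Hnf4a 1.21 (SE 0.28). By edgeR's quasi-likelihood test 2788 genes passed, and 5907 had an unadjusted p under 0.05. Of the 2788, 920 had a more positive and 1868 a more negative log2 fold change in CCA than in mixed tumors. Below, a higher or lower effect in CCA means a more positive or more negative log2 fold change, not a stronger or weaker one. Library size alone moved the median by -0.51 and called 4330 genes, 150 higher and 4180 lower, and log2 Akt1 as a covariate left 0, so no call named here held with it. The 8 tumors of the larger batch ended the calls of Sox9, Alb and Hnf4a, among others, and library size alone that of Hnf4a. The count fell to 1058 without YAP-S mixed tumor 2, 1323 without YAP-S CCA tumor 5, 1564 without YAP-S mixed tumor 9, 1744 without YAP-S CCA tumor 4 and 1749 without YAP-SY mixed tumor 5.

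YAP-TEAD targets had a lower effect in CCA in 13 of 21 genes (15 adjusted over the list alone; median -1.54, 0.0942 with an estimated correlation), and fibroblast markers in 12 of 18 (15 adjusted over the list alone; median -1.92, 0.0942), as in Acta2 (-2.42). TGF-beta response genes did so in 7 of 12 by either adjustment (median -1.21, 0.0942), cholangiocyte markers in 7 of 20 (11 adjusted over the list alone; -1.73, 0.201), as in Cd24a (-2.66), and antigen presentation genes in 9 of 12 (10 adjusted over the list alone; -3.39, 0.201), as in H2-Ab1 (-3.58). NF-kB genes had a lower effect in 10 of 17 (13 adjusted over the list alone; -1.89, 0.162), with Vcam1 at -2.39. Hepatocyte identity genes had a higher effect in 12 of 22 (15 adjusted over the list alone; median 1.14, 0.201), complement and coagulation genes in 15 of 23 (16; 1.19, 0.201) and fatty acid oxidation genes in 9 of 15 (10; 0.84, 0.201). The last value of each group is the adjusted p with an estimated correlation. In all 29 lists passed camera, 11 higher and 18 lower; 0 passed with an estimated correlation (smallest adjusted p 0.0942), and fry called 19. Under library size alone the medians of fatty acid synthesis and cholesterol synthesis genes turned to -0.08 and -0.02. Of the panel 9 genes passed, or 14 adjusted over the list alone. Besides those above these were Ttr (0.83) and Ptprc (-1.55). Ttr lost its call in 10 of 12 leave-outs (lowest value 0.70), that is without any tumor but YAP-SY CCA 6 and YAP-SY mixed 9. Ptprc lost it in 7 (highest value -1.02, without YAP-SY mixed tumor 5), namely without YAP-S mixed 2 or 9, YAP-S CCA 4 or 5, YAP-SY CCA 1 or 6 or YAP-SY mixed 5. A batch term ended the calls of both.

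The 4 largest positive differences were in Moxd1 (11.6) and the major urinary proteins Mup17 (4.17), Mup18 (3.77) and Mup15 (3.74), whose reads close paralogs may share. Moxd1 was at 22.1 ± 25.7 CPM in YAP-S and 0.916 ± 0.872 CPM in YAP-SY mixed tumors (n = 3), the opposite order to CCA. Among the largest negative differences were those in Akr1cl (-6.24), Wisp2 (-5.48) and Cdh15 (-5.39). Mup17 and Mup18 lost their calls without YAP-S mixed tumor 2 (3.78 and 3.27) or YAP-S CCA tumor 5 (3.99 and 3.6). Mup15 lost its call in 9 of 12 leave-outs (2.60 to 4.36), all but those of YAP-S mixed 7, YAP-SY CCA 8 and YAP-SY mixed 3, and with a batch term. Limma-voom did not call Moxd1 or the 3 Mup genes. Cdh15 lost its call in 7 (-5.52 to -4.29), without YAP-S mixed 2 or 9, YAP-S CCA 3, 4 or 5, YAP-SY CCA 6 or YAP-SY mixed 9. With its call kept, Moxd1 ran from 10.2 without YAP-SY CCA tumor 1 or YAP-S mixed tumor 9 to 12.5 without YAP-SY mixed tumor 3. Without YAP-SY mixed tumor 9 Akr1cl had -5.24 and Wisp2 -4.25, and Akr1cl had -7.48 without YAP-SY CCA tumor 1. Without YAP-SY CCA tumor 8 Wisp2 had -6.12, Col1a1 -3.85 and H2-Ab1 -4.29, and Cdh15 had -7.19 without YAP-S mixed tumor 7. Across genes, which are not independent replicates, the log2 fold changes in CCA and in mixed tumors had a Pearson correlation of 0.07 and a Spearman correlation of 0.18. The Pearson value was -0.09 without YAP-S mixed tumor 7, -0.08 without YAP-SY mixed tumor 3, 0.17 without YAP-SY mixed tumor 5 and 0.21 for genes with a mean of at least 10 CPM. Of the 7171 genes called in CCA, 64.2% had the same sign in mixed tumors, against 58.5% of all 18318 tested genes.

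**Figure D4:**
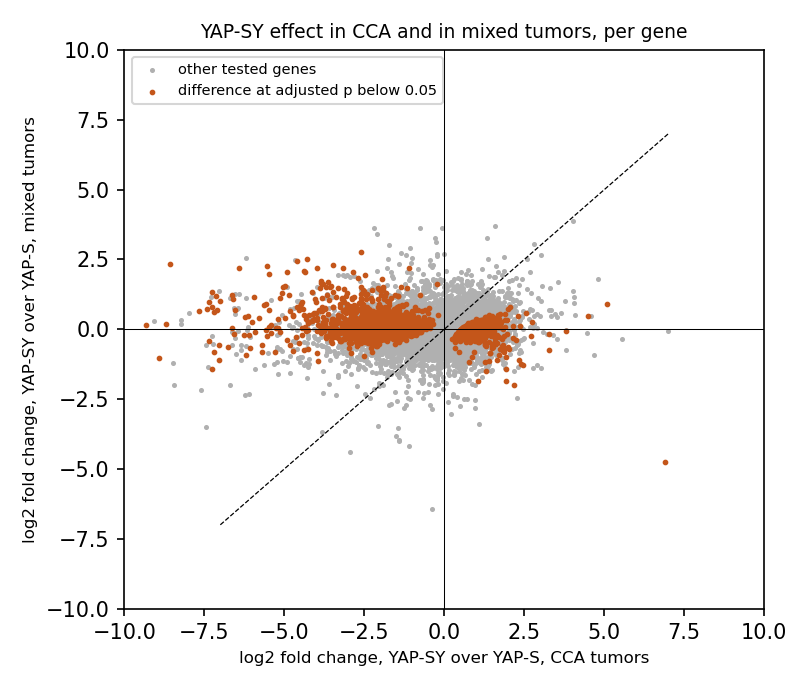
Log2 fold change of YAP-SY over YAP-S in mixed tumors (vertical axis) against that in CCA tumors (horizontal axis) for each of 18318 tested genes; colored points are the 2788 genes whose difference passed, and the dashed line marks equal values. Most colored points spread along the horizontal axis, and the point at the lower right is Moxd1, at 6.89 in CCA.

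Over both histologies, the mean effect of YAP-SY, Clec2h was the largest rise without overlap in either histology (log2 fold change 2.83, SE 0.40, adjusted p 0.00131). Abcd2 rose by 1.96, the circadian repressor Nr1d2 by 1.54, and Zyg11a, Gprin3 and Acpp by 1.36, 1.27 and 1.27. Among the falls were Cpe (-1.93), a peptide processing enzyme, Ndrg1 (-1.54), a hypoxia response gene, Htra3 (-1.38), Ppard (-1.24), Npdc1 (-1.23), Adamtsl2 (-1.13) and the chemokine gene Cxcl14 (-1.12). Cyp4a14, Cyp2c38 and Saa2 belong to the same set, with values left uncertain by close paralogs. By edgeR's quasi-likelihood test 4555 genes passed, 2158 higher and 2397 lower, and 6993 had an unadjusted p under 0.05. Library size alone moved the median by -0.31 and called 6652, 578 higher and 6074 lower. In 3.02% of the genes the models did not overlap within both histologies in the same direction. Chance gives 0.5% only where neither histology has an effect. With 52.6% of the genes without overlap in CCA, the CCA effect alone raises that share. The 3.02% therefore does not show an effect shared by both histologies. The count fell to 2947 without YAP-S CCA tumor 5, 2764 without YAP-S mixed tumor 7 and 2763 without YAP-SY mixed tumor 3.

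YAP-TEAD targets fell in 15 of 21 and rose in 2, by either adjustment (median -0.82, 0.141 with an estimated correlation), with Ctgf at -1.46 and Cyr61 at -0.84; the risers, Dock5 and Nt5e, were named after their values were seen and lost their calls under library size alone. Fibroblast markers fell in 16 of 18 by either adjustment (median -1.11, 0.141), as in Acta2 (-1.44), and all 20 G2 and M phase genes fell by either adjustment (median -0.80, 0.229), as in Aurkb (-1.24). Hepatocyte identity genes rose in 16 of 22 (17 adjusted over the list alone; median 0.69, 0.192), cytochrome P450 genes in 12 of 16 (14 adjusted over the list alone; 0.90, 0.155), as in Cyp4a10 (1.43), and fatty acid oxidation genes in 12 of 15 (13 adjusted over the list alone; 0.65, 0.141). The last value of each group is the adjusted p with an estimated correlation. In total 27 lists passed camera, 11 higher and 16 lower; 0 passed with an estimated correlation (smallest adjusted p 0.141), and fry called 27. Of the panel 13 genes passed, or 15 adjusted over the list alone. Since the difference between the histologies passed for many of these genes, the mean is not the effect in each histology. Of the 23 genes named as called over both histologies, log2 Akt1 as a covariate ended 10 calls, no histology term 8 and the 8 tumors of the larger batch 8. The animal number as a replicate block is no check of these calls, because its YAP-SY effect rests on a single pair of mixed tumors.

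Within YAP-S, CCA and mixed tumors were compared to ask what sets the histologies apart. In the fit of all 12 tumors no gene passed, and no list passed with an estimated correlation. The lists named next passed camera at its preset correlation. Fibroblast markers had a median of 0.95 in CCA over mixed tumors, with 0 genes past the threshold and 15 of 18 higher adjusted over the list alone (0.144 with an estimated correlation); the matrix gene Col5a1, for example, had 1.29. YAP-TEAD targets had a median of 0.62 (14 of 21 higher adjusted over the list alone, 0.144), NF-kB genes 0.84 (10 of 17, 0.144), with Vcam1 at 1.32, and Notch genes 0.59 (7 of 13, 0.144). Antigen presentation genes had a median of 1.54 (9 of 12, 0.345), as in H2-Ab1 (1.68), and hepatocyte identity genes -0.48 (8 of 22 lower, 0.345), as in Apob (-0.90). By edgeR's quasi-likelihood test in that fit 0 genes passed, with a smallest adjusted p of 0.0525, and 3636 had an unadjusted p under 0.05. By the same test 2393 passed in a fit of the YAP-S tumors alone and 117 to 711 under other scalings or count filters. The count stayed at 0 with a batch term, with log2 Akt1 as a covariate and in every leave-out of a tumor. DESeq2's own test called 1435 genes and limma-voom 3609. The groups did not overlap in 37.8% of the genes, against 10% by chance. By camera 26 lists passed, 16 higher and 10 lower; 0 passed with an estimated correlation (smallest adjusted p 0.144), and fry called 7. Library size alone moved the median by 0.22 and turned that of fatty acid synthesis genes to 0.06. Of the panel 0 genes passed, or 5 adjusted over the list alone.

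Within YAP-SY some YAP targets, stromal genes and dividing cell genes were lower in CCA than in mixed tumors. No list passed with an estimated correlation. For the first 2 the list medians in YAP-S pointed the other way, but no gene passed there by edgeR's quasi-likelihood test. Ctgf had a log2 fold change of -1.73 (SE 0.27, adjusted p 0.0129) and Ankrd1 -2.26 (SE 0.35, adjusted p 0.0136). Tgfb3 had -2.18, Lox -1.79, Acta2 -1.77, Postn -1.22 and Wfdc18, a secreted protease inhibitor gene, -3.46. Egfr, the receptor of epidermal growth factor, rose 2.94-fold, from 463 ± 167 in mixed to 1360 ± 251 CPM in CCA tumors (n = 3), and Pim1, a survival kinase, 2.19-fold. By edgeR's quasi-likelihood test 532 genes passed, 38 higher and 494 lower, 3951 had an unadjusted p under 0.05, and the groups did not overlap in 20.1% of the genes, against 10% by chance. Leaving out a tumor also lowers power, which was not told apart from the weight of that tumor. No call held without YAP-SY CCA tumor 6, although 3767 genes still had an unadjusted p under 0.05. Without it 0 genes passed, and the values of Ctgf, Ankrd1, Tgfb3, Lox, Acta2, Postn, Wfdc18 and Pim1 were -1.53, -1.99, -1.92, -1.73, -1.63, -1.39, -3.21 and 1.07. Without YAP-SY CCA tumor 1, YAP-SY mixed tumor 5 or YAP-SY CCA tumor 8 the counts were 109, 113 and 319. With the 8 tumors of the larger batch, with log2 Akt1 as a covariate or in a fit of the YAP-SY tumors alone, no gene named here kept its call. Egfr lost its call in 5 of 6 leave-outs (1.39 to 1.63), all but that of YAP-SY mixed tumor 3. DESeq2 called 1720 genes and limma-voom 16, and library size alone moved the median by -0.29 and called 2006, 18 higher and 1988 lower.

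In that comparison G2 and M phase genes fell in 6 of 20 (18 adjusted over the list alone; median -0.90, 0.209 with an estimated correlation) and YAP-TEAD targets in 6 of 21 (13 adjusted over the list alone; -0.67, 0.183). Fibroblast markers fell in 6 of 18 (11 lower and 1 higher adjusted over the list alone; -0.91, 0.209). Hepatocyte identity genes had a median of 0.58 with 0 past the threshold (9 of 22 higher adjusted over the list alone, 0.209), and complement and coagulation genes 0.60 with 0 (13 of 23, 0.209). Camera called 23 lists, 9 higher and 14 lower; 0 passed with an estimated correlation (smallest adjusted p 0.183), and fry called 20. Of the panel 5 genes passed, all lower (13 adjusted over the list alone): Ctgf, Ankrd1, Cyr61, Sox9 and Mki67. The last 3 lost their calls with a batch term and without YAP-SY CCA tumor 1, 6 or 8 or YAP-SY mixed tumor 5, and Cyr61 and Mki67 also without YAP-SY mixed tumor 3. Their values in these leave-outs were -0.84 to -0.68 in Cyr61, -1.88 to -1.06 in Sox9 and -1.24 to -0.77 in Mki67. Across genes, which are not independent replicates, the CCA over mixed log2 fold changes in YAP-S and in YAP-SY had a Pearson correlation of -0.40 and a Spearman correlation of -0.47. The sign was opposite in 70.5% of all genes and in 93.6% of the 532 called in YAP-SY.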

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

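The tests of shifted scales and of sinusoid markers were chosen only after the result was seen. The Akt1 covariate fit and the scalings by library size alone and by upper quartile were added after the data had been seen.

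The effect of YAP-SY differed between CCA and mixed tumors by a test of the difference itself. It passed for 2788 genes and 29 gene lists, although 0 lists passed with an estimated correlation (smallest adjusted p 0.0942). Among panel genes the difference of log2 fold changes, CCA minus mixed, was -3.58 in Ankrd1, -2.24 in Ctgf, -1.26 in Cyr61, -3.17 in Col1a1, -2.12 in Sox9 and -1.55 in Ptprc. It was 1.26 in Alb, 1.21 in Hnf4a and 0.83 in Ttr. The largest positive differences were 11.6 in Moxd1, 4.17 in Mup17, 3.77 in Mup18 and 3.74 in Mup15. Among the largest negative ones were -6.24 in Akr1cl, -5.48 in Wisp2 and -5.39 in Cdh15. In Mup17, Mup18, Mup15, Cdh15, Ptprc and Ttr leaving out single tumors ended the call, with the tumors and values given among the results.

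For the 2788 genes chance is not excluded by regrouping: 9 of 100 splits within histology, the real one included, gave as many genes, with 5821 in the highest other split. Over both histologies 4 of 100 splits gave at least the real 4555 genes, a share under 0.05, with 5386 in the highest other. The other splits as large, 8 for the difference and 3 over both histologies, kept the CCA tumors grouped as labelled and regrouped mixed tumors only, which leaves the whole CCA effect in place. Drawn splits that regrouped CCA tumors put that effect into the spread and gave 0 genes in both tests. Both counts of splits thus follow the CCA tumors and say little about chance in the difference of effects or in the mean effect. For the comparisons of 3 with 3 tumors, the 10 splits are too few for a share under 0.05. In CCA 1 of 10 splits, the real one, reached 7171 genes and the highest other gave 0. CCA against mixed tumors in YAP-SY had 1 of 10, with 532 real and 296 in the highest other. In mixed tumors and in YAP-S all 10 of 10 splits gave 0, as the real ones did by edgeR's quasi-likelihood test. There 551 and 3636 genes had an unadjusted p under 0.05, DESeq2 called 9 and 1435, and limma-voom 0 and 3609.

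The broad difference between YAP-SY and YAP-S CCA tumors was weighed against 4 technical explanations. A single shift of the scale could not account for all of it. Over shifts of the YAP-SY CCA libraries by -1 to 1 on the log2 scale, at least 6915 genes were called (4910 to 6654 over leaving out single CCA tumors). With 3358 genes called higher and 3813 lower on the TMM scale, this outcome was largely set beforehand. How far abundant liver transcripts shift the scale, and so which genes count as higher or lower, stays open: 99.5% of the called genes kept call and direction under DESeq2 size factors, 96.7% under upper quartile factors and 63.8% under library size alone, which moves all genes by about the same amount. Whether fewer cells with the AKT plasmid contribute stays open. With log2 Akt1 as a covariate the fold changes kept 0.868 of their size, or 0.807 to 0.946 over leaving out single CCA tumors. Of them 99.3% kept their direction. That fit cannot decide the question, because its Akt1 slope comes only from differences between tumors of the same group. Counts from the plasmid and from the animals' own Akt1 also cannot be told apart. Calls went from 7171 to 601 as the median SE rose from 0.23 to 0.34. That count was 0 without YAP-S CCA tumor 4 or YAP-SY CCA tumor 8, where the median SE was 0.41 and 0.42, and 234 to 863 without any other CCA tumor. More surrounding liver in the YAP-SY nodules may contribute and stays open, as does the change in YAP itself, which was not tested apart from it: markers of sinusoidal endothelium and Kupffer cells had a median log2 fold change of 0.766 (0.545 to 0.84 over leaving out single tumors), 0.601 of the hepatocyte median of 1.27, but 0.308 of it under library size alone.

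That marker list held Stab2, Clec4g, Oit3, Lyve1, Clec4f, Vsig4, Timd4, Cd5l and Marco, all 9 of which are in the endothelial or macrophage list and are carried by normal liver. The most abundant were Stab2 (72.6 to 109 CPM), Clec4f (73 to 106 CPM) and Cd5l (56.9 to 101 CPM). Of the 9, 5 were higher in YAP-SY CCA past the threshold and 0 lower; Marco had a log2 fold change of -0.0737 (adjusted p 0.83). Other members of the endothelial and macrophage lists fell, among them Vwf, Plvap, C1qa, C1qb, C1qc and Cd68, and neither list passed camera. As the 9 markers were chosen after the result was seen, their median does not measure the share of surrounding liver. The labels name no sorting or dissection that would remove surrounding liver.

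The absence of called genes between YAP-SY and YAP-S mixed tumors was weighed against 2 technical explanations, and both stay open. Spread shared with the CCA tumors was tested by a fit of the 6 mixed tumors alone. It gave 614 genes at an unadjusted p under 0.05 where chance gives 876, but 410 to 1721 over leaving out single tumors, being 1238 without YAP-SY mixed tumor 5 and 1721 without YAP-SY mixed tumor 9. Low power was tested on simulated counts, where 34% of 2-fold and 76% of 4-fold changes were called. A biological difference between the histologies in how they respond to the lost tyrosine is open as well and was tested only as the difference of effects.

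The SB1 cells enter no comparison. Their YAP-TEAD targets had a median of 97.4 CPM and their cholangiocyte markers one of 31.3 CPM, above the 0.098 to 0.12 CPM that 3 counts amount to in these libraries.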

How the results depend on the processing

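Library size alone, upper quartile factors, the batch term, the fit of 8 tumors and the Akt1 covariate were chosen after seeing the data. The 175 calls of named genes, each gene counted once per comparison, had 3584 values under alternatives, the replicate block included. Of these values 3148 kept direction and call, 429 kept only the direction and 7 reversed. With the Akt1 covariate these were Mup16 (-0.345), Serpina3j (-0.656) and Glul (-0.0855), and under library size alone Dock5 (-0.0511), Clec4f (-0.0246), Cdh2 (-0.0914) and Lats1 (-0.202). In CCA (7171 genes) a log2 change of at least 1 left 3780, the 8 tumors 3443 and Akt1 601; other settings stayed within 1.5 times, single leave-outs at 5121 to 6869. In mixed tumors DESeq2 gave 9. Over both (4555) a log2 change of at least 1 left 1092, no Mut1 tumors 2764, the 8 tumors 333, Akt1 302, no histology term 356 and leave-outs 2763 to 5198. A replicate block by animal number left 86, of which 29 were shared with the unblocked result. Only numbers 3, 5 and 9 occur in both models, and whether they pair tumors is not settled. For the difference (2788) library size alone gave 4330, the batch term 1771, the 8 tumors 744, Akt1 0 and leave-outs 1058 to 3077. In YAP-S (0) DESeq2 size factors gave 117, DESeq2 1435, voom 3609, no filter 570, 1 CPM in 3 libraries 269, no Mut1 tumors 200, library size alone 711, upper quartile 137 and a fit of those tumors alone 2393. In YAP-SY (532) DESeq2 gave 1720, voom 16, no filter 859, library size alone 2006, the batch term 138, the 8 tumors 0, Akt1 0, a fit of those tumors alone 0 and leave-outs 0 to 595. With an estimated correlation 0 lists passed in each of the 6 comparisons. The correlation between CCA and mixed effects was 0.214 at a mean of 10 CPM or more and -0.094 to 0.173 over leave-outs (-0.094 without YAP-S mixed tumor 7, -0.0819 without YAP-SY mixed tumor 3). A stricter size limit lowers a count by its definition. Fewer tumors tested and the wider SE with Akt1 may account for part of the other lower counts. That was not told apart from the weight of the tumors left out or of the added term. Elsewhere the cause was not tested. The SY1 against SB1 comparison and the cell line genes in tumors were not run, and a pseudocount alternative had no use with counts. In simulated counts 10% of 2-fold differences of effect between the histologies were called, 34% to 38% of 2-fold changes between 3 and 3 tumors, and 63% over both histologies.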

Other observations

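The markers in the next paragraph were chosen after their values were seen, and no test was added for them.

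Macrophage markers moved apart between the CCA tumors. The macrophage list as a whole did not pass camera. In YAP-SY CCA its higher members included Timd4 (0.89 on the log2 scale), Vsig4 (0.91) and Cd5l (0.83), markers of Kupffer cells. Those are the resident macrophages of liver. Mrc1, another macrophage gene, was higher by 0.93. Marco, also a Kupffer cell marker, was not higher (log2 fold change -0.07, adjusted p 0.83 by edgeR's quasi-likelihood test). The complement genes C1qa, C1qb and C1qc, made by macrophages, had log2 fold changes of -1.66, -1.46 and -1.54. Trem2, a lipid receptor of macrophages, had -1.66 and Cd68 -0.89. Which macrophages these RNAs came from was not tested. Among endothelial markers Vwf (-1.62) and Plvap (-1.08), which mark larger or newly formed vessels, were lower, and Clec4g, a lectin of liver sinusoids, was higher (0.77). Library size alone ended the calls of Timd4, Vsig4, Mrc1, Cd5l and Clec4g and turned Clec4f, another Kupffer cell marker (0.53), to -0.02. The 8 tumors of the larger batch ended the calls of Timd4, Cd5l, Clec4g, Clec4f and Trem2, and a minimum log2 change of 1 those of the higher markers and Cd68. With log2 Akt1 as a covariate no marker named here but Vwf kept its call. Clec4f was also lost with a batch term, with upper quartile factors and with no count filter, and both Clec4 genes without the tumors with a second naming of YAP-SY. Clec4g lost its call without YAP-S CCA tumor 3 or 5 or YAP-SY CCA tumor 1 or 8 (0.54 to 0.80), and Clec4f without any of the 6 tumors (0.44 to 0.60).

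The 3 SB1 cell samples, at 30541185, 25341968 and 26281442 counts, held RNA of YAP targets and bile duct genes and little of hepatocyte genes. Of 22 YAP-TEAD targets 21 reached 1 CPM, with Ctgf, named Ccn2 in that table, at 491 ± 59.5 and Ankrd1 at 327 ± 116 CPM (SD, n = 3). Of 20 cholangiocyte markers 16 did, among them Krt19 at 1430 ± 341 and Spp1 at 905 ± 154 CPM, while Cldn7 was at 0 in all 3 samples, which allows up to 0.098 to 0.12 CPM by counting error. Hepatocyte identity genes reached 1 CPM in 7 of 22, with a median of 0.241 CPM. Macrophage markers had a median of 0.0066 CPM and T and NK cell markers one of 0. These counts are raw, unlike those of the tumors, and were not compared with them.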
